A study of Homo sapiens with 36 samples.

How the data were processed

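RNA of THP-1, a human monocytic leukaemia cell line, was sequenced as 100 bp paired-end reads in 36 libraries, made with a directional mRNA kit from 500 ng of RNA with an integrity number above 7, per the labels' protocols. The cells had been made into macrophages with 150 nM of the phorbol ester PMA for 24 h and polarized towards the inflammatory M1 state with 20 ng/mL interferon-γ and 10 pg/mL lipopolysaccharide for 48 h, and were then given an extract or PBS for 24 h. The table deposited by the authors holds expected counts, which are estimated read counts per gene that need not be whole; 9.93% of its values were fractional. FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 and the genome build GRCh38 (hg38) are named in the submitters' processing notes, without their roles. The annotation release and whether counting used the strand are not given in the sources used here, so antisense genes and genes that share reads with a near copy are reported as uncertain.

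The table lists 60675 Ensembl gene identifiers. All 36 value columns were matched to samples by name, with 0 columns left without a sample and 0 lines without a gene. Symbols were found for 41995 identifiers, and positions were taken from GENCODE release 29 on GRCh38. The libraries held 30.6e6 to 45.5e6 expected counts each. There were 12 groups of 3 libraries: PBS vehicle, 5 extracts at 500 and 125 µg/mL, and a mixture of 4 of the extracts at 125 µg/mL each, 500 µg/mL in all. The labels also carry a numbering that divides the libraries into 3 sets of 12. Set 1 holds vehicle, BJIKT at both concentrations and ginseng at 500 µg/mL, set 2 holds ginseng at 125 µg/mL, astragalus at both concentrations and atractylodes at 500 µg/mL, and set 3 holds atractylodes at 125 µg/mL, licorice at both concentrations and the mixture. What the sets stand for is not given in the sources used here. The protocols name plates of 12 wells, which equals the number of libraries in a set, but nothing says that a set was a plate.

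Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the groups, which left 18154, libraries were scaled with TMM, and 1 robust quasi-likelihood fit of all 36 libraries without covariates was used for every comparison (24 residual degrees of freedom, common biological coefficient of variation 5.04%). Adjusted p-values are Benjamini-Hochberg values from the edgeR quasi-likelihood test over the 18154 genes, with 0.05 as threshold. Each treatment was compared with vehicle, each extract at 500 with 125 µg/mL, and the mixture with BJIKT at 500 µg/mL. The mixture's log2 change was also compared with the sum of the changes of its 4 components at 125 µg/mL, and the 4 ingredients at 500 µg/mL were compared in a joint F test. Log2 fold changes (log2FC) are given with standard errors (SE), and levels as CPM (counts per 1e6 counts of the scaled library), mean ± SD over 3 libraries.

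Gene lists (41 with at least 5 tested members) were fixed from textbook knowledge and tested with camera in limma 3.58.1 on log2 CPM with prior count 2, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. List p-values are Benjamini-Hochberg adjusted over the 41 lists of a comparison. Members are counted at 0.05 over all genes tested and again adjusted over the list alone. Of the lists, 5 are markers of cells other than macrophages.

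Named genes followed a fixed rule. A gene needed a symbol, a mean log2 CPM of at least 1, an adjusted p under 0.05 and complete separation of the libraries compared, and was ranked by log2FC. The 8 highest and 8 lowest were taken for BJIKT and the mixture at 500 µg/mL, 5 and 5 for each ingredient at 500 µg/mL, 3 and 3 for each treatment at 125 µg/mL and each pair of concentrations, and 6 and 6 for the mixture against BJIKT. For the mixture against the sum 4 and 4 were taken without the separation rule, and for the F test the 8 with the smallest p among genes with a log2 range of at least 1. Up to 4 members of a described list could be named, those with the smallest p, and 14 macrophage, stress and metabolic genes were set to be given for BJIKT and the mixture. Of these, MRC1 was not among the tested genes.

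The alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, a fit of only the groups compared, each library of the groups compared left out in turn, for correlations only the genes with a mean log2 CPM of at least 3, and, chosen after seeing the data, a correction for transcript GC content and length and a library score as covariate. That score, the library gradient, is the mean centred log2 CPM of the 50 genes that followed TMEM160 most closely within groups, so that for TMEM160 and those 50 genes the covariate is no test. Replicates were compared before averaging, and no pair was close enough to be 1 library deposited again (chi-square per gene 3.227 to 13).

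The methods were tested on simulated data drawn from the real means and library sizes, with 200 changed genes. Each gene was drawn independently, without a difference between label sets, a library gradient or a GC and length trend. False calls from these sources are therefore not covered. For BJIKT at 500 µg/mL against vehicle, edgeR recovered 46% of the genes changed 1.2-fold, 88% at 1.5-fold, 100% at 2-fold and 98% at 4-fold, and 5 of 171 calls were false, over 17945 genes. For the mixture against the sum the shares were 0%, 44%, 78% and 98%, and for the F test 50%, 92%, 100% and 100%. Correlations between responses that share the vehicle libraries are given beside values from 20 simulations of unchanged groups.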

Results

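Transcript levels were measured in THP-1 cells, a human monocytic leukaemia line, that had been made into M1-polarized macrophages and kept for 24 h with a water extract or with PBS as vehicle. Bojungikki-tang (BJIKT) is a decoction of several herbs used in East Asian medicine, and 4 of its ingredients, Panax ginseng, Astragalus mongholicus, Atractylodes japonica and Glycyrrhiza uralensis (licorice), were also given alone, each at 500 and 125 µg/mL. A mixture of the 4 ingredients held 125 µg/mL of each. The 36 libraries formed 12 groups of 3, held 30.6e6 to 45.5e6 expected counts each and gave 18154 genes for testing. Nothing in the labels says that the replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. The vehicle libraries all carry the labels of set 1, so that in 8 of the 11 comparisons with vehicle (ginseng at 125 µg/mL, all astragalus, atractylodes and licorice groups, and the mixture) treatment and label set cannot be told apart. Only BJIKT at both concentrations and ginseng at 500 µg/mL were compared with vehicle within a set.

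On the first principal component (13.9% of the variance of 2000 genes) the 3 libraries of BJIKT at 500 µg/mL lay between 20.34 and 23.45 and those of ginseng at 500 µg/mL between 18.39 and 19.09, against -14.5 to -9.62 for vehicle. Licorice at 500 µg/mL stood apart on the second component (7.34%), at 21.59 to 27.22. FTH1 and FTL, the subunits of the iron store ferritin, and CHI3L1, a secreted macrophage glycoprotein, were the most abundant transcripts with 2.11%, 2.05% and 1.86% of all counts.

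**Figure D1:**
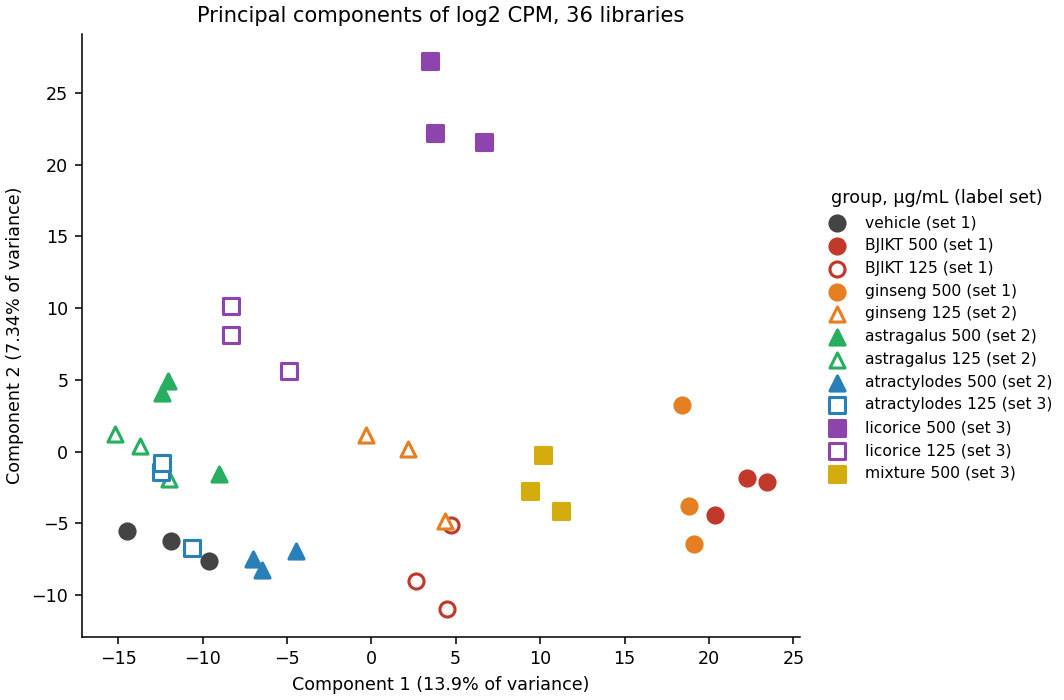
Scores of the 36 libraries on the first (13.9% of variance) and second (7.34%) principal components of log2 CPM of 2000 genes, 1 point per library, coloured by group. BJIKT and ginseng at 500 µg/mL lie at the right (18.39 to 23.45 on the first component), vehicle at the left (-14.5 to -9.62), and licorice at 500 µg/mL at the top (21.59 to 27.22 on the second).

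BJIKT at 500 µg/mL was compared with vehicle to see what the whole decoction does to M1 macrophages. Among genes with a symbol and a mean log2 CPM of at least 1, STC1, a secreted glycoprotein hormone, rose most (log2FC 3.55, SE 0.17, adjusted p = 5.37e-15; 66.3 ± 11 CPM against 5.7 ± 1 in vehicle, n = 3 each). Next came the neutrophil chemokine CXCL5 (3.18; 310 ± 35 against 34.2 ± 4.6 CPM), the chemokine CCL1 (3.09), the prostaglandin synthase PTGS2 (2.67; 138 ± 13 against 21.7 ± 3.4 CPM), CXCL3 (2.66), the growth factor NRG1 (2.63) and CXCL1 (2.62). The cytokine IL1B rose by 2.46 (SE 0.14, adjusted p = 6.37e-13; 3600 ± 290 against 653 ± 150 CPM). The lowest of these genes was BLOC1S5-TXNDC5 (-4.01, SE 1.3, adjusted p = 0.0156), a readthrough gene that shares reads with its neighbours and is therefore uncertain. Its adjusted p was 0.0515 without BJIKT at 500 µg/mL replicate 2 and 0.0704 without replicate 3. NUPR1, a stress-induced transcriptional regulator, fell by 1.86 (SE 0.084, adjusted p = 4.47e-20; 8.37 ± 0.65 against 30.4 ± 0.72 CPM). The sorting receptor SORL1 fell by 1.83, DCLK3 by 1.63, GALNT12 by 1.62, the carboxypeptidase CPVL by 1.57, WIPF3 by 1.53 and PHGDH, the first enzyme of serine synthesis, by 1.49. STC1 (ENSG00000159167) lies on chromosome 8 at 23841915 to 23854807, CXCL5 (ENSG00000163735) on chromosome 4 at 73995642 to 73998779. IL1B (ENSG00000125538) lies on chromosome 2 at 112829751 to 112836903 and NUPR1 (ENSG00000176046) on chromosome 16 at 28532708 to 28539174 (GRCh38).

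Among the genes set in advance, the cytokine TNF rose by 2.28 (177 ± 11 against 36.5 ± 3.7 CPM), the neutrophil chemokine CXCL8 by 2.35 (8830 ± 410 against 1730 ± 250 CPM). IL6 rose by 3.20 at a very low level (0.556 ± 0.064 against 0.0593 ± 0.043 CPM). The costimulator CD80 rose by 1.75, the haem oxygenase HMOX1 by 0.80 and CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor (AhR), by 1.41 (SE 0.04, adjusted p = 2.91e-26; 194 ± 6.2 against 73 ± 1.3 CPM). The scavenger receptor CD163, an M2 marker, fell by 0.78. The interferon-induced chemokine CXCL10 (-0.40, adjusted p = 0.246), CCL2 (0.50, 0.253), CD86 (0.25, 0.294), the sterol enzyme HMGCS1 (-0.01, 0.899) and the metallothionein MT2A (-0.24, 0.0683) did not pass. Without vehicle replicate 1 or without BJIKT at 500 µg/mL replicate 1 MT2A passed (0.0262 and 0.0261).

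The inflammatory lists rose together in BJIKT at 500 µg/mL. Of 22 NF-κB response genes 19 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 7.12e-17), with TRAF1 at 0.86, the inhibitor NFKBIA at 0.90 and TNIP1 at 0.83. Of 24 chemokines 15 rose (15 rose and 1 fell adjusted over the list alone; 2.18e-12), such as CXCL2 (2.34) and CCL3 (1.84). Of 17 inflammatory cytokines 11 rose and 2 fell, with the same counts adjusted over the list alone (1.27e-06), such as IL1A (3.23), LIF (2.17) and, at a low level, CSF2 (4.92). Anti-inflammatory feedback genes rose as well, 13 of 18 with 1 lower (13 and 2 adjusted over the list alone; 1.16e-06), among them the deubiquitinase TNFAIP3 (0.57), the phosphatase DUSP1 (0.72) and the decoy receptor IL1R2 (1.65). Of 7 AhR targets 6 rose and 1 fell by both counts (1.16e-06), with TIPARP at 0.72 and the receptor's repressor AHRR at 0.65. Of 20 genes of the unfolded protein response of the endoplasmic reticulum 14 rose and 2 fell (15 and 3 adjusted over the list alone; 4.72e-05), such as the chaperone HSPA5 (0.46). Of 29 genes of the ATF4 and amino acid response 25 fell and 3 rose (26 and 3 adjusted over the list alone; 8.8e-13, but adjusted p = 0.0784 with an estimated correlation), with CBS at -0.47 and PSPH at -0.87 but the cystine carrier SLC7A11 at 1.12. The interferon-induced genes went down, 15 of 30 lower (16 lower and 1 higher adjusted over the list alone; 4.72e-05, adjusted p = 0.371 with an estimated correlation), such as IFIT2 (-0.78) and IFIT1 (-0.83). Cell cycle genes fell in 31 of 34 cases (33 adjusted over the list alone; 3.53e-13, adjusted p = 0.0607 with an estimated correlation), with TYMS at -0.73 and BIRC5 at -0.85. Of 36 ribosomal protein genes 23 fell (25 adjusted over the list alone; 2.69e-06, adjusted p = 0.273 with an estimated correlation), and their share of all counts was 2.32% ± 0.069 against 2.77% ± 0.201 in vehicle (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

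In all, 6060 of 18154 genes (33.4%) passed in BJIKT at 500 µg/mL, 2999 higher and 3061 lower, 553 of them at least 2-fold. At 125 µg/mL 1731 genes passed (880 higher, 851 lower), among them CCL1 (2.02), CXCL5 (1.81) and NRG1 (1.47) higher and the nuclear factor TOX2 (-0.95), NUPR1 (-0.81) and HOXA13 (-0.80) lower. TNF rose by 1.06, IL1B by 1.3 and CXCL8 by 1.14. Of 22 NF-κB genes 18 rose (19 adjusted over the list alone; camera adjusted p = 3.46e-22) and of 24 chemokines 12 rose (14 adjusted over the list alone; 8.18e-17). The interferon-induced genes, lower at 500 µg/mL, were higher here, 6 of 30 by both the count over all genes and that adjusted over the list alone (2.56e-05, adjusted p = 0.4 with an estimated correlation). The count of 1731 fell to 1132 without vehicle replicate 3 and to 1045 without BJIKT at 125 µg/mL replicate 3, and was 864 in a fit of only the compared groups.

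The pair of BJIKT concentrations was compared directly for the influence of concentration, within 1 label set. Between them 2896 genes differed (1487 higher and 1409 lower at 500 µg/mL; 1812 without BJIKT at 500 µg/mL replicate 2). STC1 (2.09), the small GTPase RASL11A (1.40) and CXCL5 (1.37) were higher, and SORL1 (-1.13) and DCLK3 (-1.10) lower. The uncertain BLOC1S5-TXNDC5 (-3.93) lost its call without any 1 of the 6 libraries (adjusted p 0.0588 to 0.13). Interferon-induced genes were lower at 500 µg/mL in 23 of 30 cases (27 adjusted over the list alone; camera adjusted p = 1.66e-19), with IFIT2 at -0.80 and IFIT1 at -0.99. Cell cycle genes were lower in 31 of 34 cases (32 adjusted over the list alone; 3.75e-21). Higher were 14 of 24 chemokines, with 1 lower (15 and 2 adjusted over the list alone; 2.76e-10), and 5 of 7 AhR targets by both counts (9.14e-08).

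Ginseng at 500 µg/mL, in the same label set as vehicle, raised chemokines and lowered amino acid synthesis genes. Among genes with a mean log2 CPM of at least 1, CCL1 rose most (log2FC 3.60, SE 0.15, adjusted p = 3.85e-17, 48.5 ± 6.2 CPM). Next came CCL4L2 (2.94, uncertain because of its near-identical paralog CCL4), the stromelysin MMP10 (2.64, with 15.9 ± 5.9 against 2.54 ± 0.55 CPM) and STC1 (2.60). CCL4 followed (2.59, with 217 ± 26 against 36.1 ± 3.5 CPM) and is uncertain for the same reason as CCL4L2. NUPR1 fell by 2.16, the serine synthesis enzyme PSAT1 (chromosome 9, 78297143 to 78330093) by 2.08 (SE 0.16; 71.8 ± 5 against 304 ± 24 CPM), STC2 by 2.08, PHGDH by 1.95 and the asparagine synthetase ASNS by 1.92 (24.3 ± 2.7 against 91.8 ± 6.9 CPM). Of 29 genes of the ATF4 and amino acid response 25 fell and 2 rose by both counts, adjusted over all genes and adjusted over the list alone (camera adjusted p = 1.07e-20, adjusted p = 0.056 with an estimated correlation). Of 24 chemokines 17 rose by both counts, also adjusted over the list alone (1.02e-16), such as CCL3 (2.39) and CXCL2 (2.19). Of 22 NF-κB genes 19 rose (20 adjusted over the list alone; 1.05e-17), such as BIRC3 (1.33). Of 17 cytokines 10 rose and 2 fell by both counts (1.27e-06), such as IL1A (3.08) and TNF (1.53). Heat shock genes rose in 16 of 19 cases (17 adjusted over the list alone; 4.89e-07, adjusted p = 0.0573 with an estimated correlation), with HSPA8 at 0.66 and HSP90AB1 at 0.40. The comparison gave 5924 genes, 3013 higher and 2911 lower, 450 of them at least 2-fold.

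At 125 µg/mL ginseng gave 1739 genes (1056 higher, 683 lower), with CCL1 (2.27) and STC1 (1.64) among the highest and SORL1 (-0.89) and HOXA13 (-0.88) among the lowest. The mitochondrial protein gene TMEM160 (1.95, adjusted p = 0.0188) lost its call without vehicle replicate 1 (0.096), vehicle replicate 2 (0.0615), ginseng at 125 µg/mL replicate 2 (0.051) or replicate 3 (0.0549). The paralog SULT1A3 (-1.29, 0.0463, uncertain) lost it without any 1 of the 6 libraries (0.054 to 0.197). Immediate-early genes, the first transcripts induced by a stimulus, rose in 21 of 29 cases (24 adjusted over the list alone; camera adjusted p = 4.83e-20), such as JUNB (0.61), FOSB (1.00) and EGR1 (0.67). Of 22 NF-κB genes 16 rose (19 adjusted over the list alone; 4.94e-26), and of 24 chemokines 13 rose by both counts (4.71e-18). With GC and length correction 1023 were higher and 990 lower. The count of 1739 was 1127 without ginseng at 125 µg/mL replicate 2 and 982 with the gradient covariate.

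Between 500 and 125 µg/mL of ginseng, groups of different label sets, 3153 genes differed (1559 higher, 1594 lower). CCL4 (1.38) and CCL4L2 (1.43), both uncertain as near-identical paralogs, were higher at 500 µg/mL. So was the uncertain SULT1A3 (1.35), whose adjusted p was 0.0935 without ginseng at 500 µg/mL replicate 1, 0.0823 without replicate 3, 0.121 without ginseng at 125 µg/mL replicate 1 and 0.113 in a fit of only the compared groups. PSAT1 (-1.91), STC2 (-1.90) and ASNS (-1.81) were lower. Amino acid response genes were lower in 26 of 29 cases and higher in 1 (27 and 1 adjusted over the list alone; camera adjusted p = 4.21e-38), such as CHAC1 (-1.79) and the folate enzyme MTHFD2 (-0.69). Of 24 chemokines 17 were higher (17 and 1 lower adjusted over the list alone; 1.41e-13).

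Astragalus at 500 µg/mL lowered metallothioneins and sterol synthesis genes. MT2A, a metal-binding protein induced by zinc, fell by 1.38 (SE 0.12, adjusted p = 1.76e-10; 2.42 ± 0.33 against 6.34 ± 0.65 CPM) and MT1E by 1.13, the cytokine receptor IL21R by 1.02 and NUPR1 by 0.93. The growth factor TGFB3 rose by 0.95, the receptor CD300LB by 0.86, the fatty acid carrier FABP4 by 0.83 (SE 0.1, adjusted p = 4.71e-06) and TSPOAP1 by 0.77. Of 8 metallothionein and zinc genes 6 fell and 2 rose by both counts, also adjusted over the list alone (camera adjusted p = 0.000165). The zinc exporter SLC30A1 was at -0.34 and the zinc importer SLC39A10 at 0.41. Cholesterol synthesis genes fell in 15 of 24 cases (21 fell and 1 rose adjusted over the list alone; 1.04e-17), such as HSD17B7 (-0.51), ACAT2 (-0.44) and CYP51A1 (-0.28). Fatty acid synthesis genes fell in 9 of 14 (11 adjusted over the list alone; 8.19e-08), such as the desaturases FADS2 (-0.45) and FADS1 (-0.33). Amino acid response genes fell in 19 of 29 cases (25 adjusted over the list alone; 1.77e-17, adjusted p = 0.121 with an estimated correlation), with DDIT4 at -0.86 and TRIB3 at -0.81. The NF-κB, cytokine and chemokine lists were not called.

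Of the remaining genes named by rule for astragalus at 500 µg/mL, PTGES, a prostaglandin E synthase (-1.23, adjusted p = 0.0371), was at 0.0685 without vehicle replicate 1, 0.13 without vehicle replicate 2, 0.168, 0.0615 and 0.0542 without astragalus at 500 µg/mL replicates 1, 2 and 3, and 0.109 with the gradient covariate. TMEM160 (1.90, 0.018) was at 0.0905 without vehicle replicate 1, 0.0536 without vehicle replicate 2, 0.266 without astragalus at 500 µg/mL replicate 1 and 0.269 in a fit of only the compared groups. In all 2138 genes passed (1112 higher, 1026 lower). There were 1289 without astragalus at 500 µg/mL replicate 1 and 1359 in a fit of only the compared groups.

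Astragalus at 125 µg/mL changed the fewest genes, 290 (193 higher, 97 lower). The count was 23 without vehicle replicate 1, 173 without vehicle replicate 3, 50 without astragalus at 125 µg/mL replicate 2, 98 without replicate 3, 126 in a fit of only the compared groups and 4 with the gradient covariate. It was higher without the low-count filter and with DESeq2, and lower with GC and length correction, as given below. CCDC85B (0.81, adjusted p = 0.0103) lost its call without vehicle replicate 1 (0.0655). TMEM160 (2.29, 0.0232) lost it without vehicle replicate 1 (0.134), vehicle replicate 2 (0.0616), astragalus at 125 µg/mL replicate 2 (0.075) or replicate 3 (0.095). The transcriptional cofactor ZFPM1 (0.83), the receptor LILRA6 (-0.43), the B cell factor TNFSF13B (-0.42) and ATP6AP1L (-0.41) each lost theirs without 5 of the 6 libraries. The cholesterol synthesis list was lower, with 2 of 24 members down and 1 up (12 and 1 adjusted over the list alone; camera adjusted p = 0.000112, adjusted p = 0.602 with an estimated correlation).

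Between the astragalus concentrations, within 1 label set, 267 genes differed (101 higher, 166 lower). MT2A (-1.14, adjusted p = 1.94e-07), MT1E (-0.94) and NUPR1 (-0.67) were lower at 500 µg/mL, FABP4 (0.67) and TSPOAP1 (0.55) higher. The muscle protein gene NEB (0.62, 0.0257) lost its call without astragalus at 500 µg/mL replicate 1 (0.107) or 2 (0.0777) or at 125 µg/mL replicate 1 (0.141) or 2 (0.101), and in a fit of only the compared groups (0.0679). Cholesterol synthesis genes were lower in 7 of 24 cases (16 adjusted over the list alone; camera adjusted p = 1.63e-15). Amino acid response genes were lower in 14 of 29 (25 adjusted over the list alone; 1.15e-27). Of 8 metallothionein and zinc genes 3 were lower and 1 higher (6 and 1 adjusted over the list alone; 5.48e-05). With GC and length correction 189 were higher and 187 lower, and with DESeq2 216 and 230. The count of 267 was 106 and 134 without astragalus at 500 µg/mL replicates 1 and 2, and 94 and 89 without astragalus at 125 µg/mL replicates 1 and 3. It was higher without the low-count filter, as given below.

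Atractylodes at 500 µg/mL raised metallothioneins and some chemokines. MT2A rose by 0.97, MT1X by 1.18 and MT1E by 0.79, and of the 8 metallothionein and zinc genes 7 rose and 1, SLC39A10 (-0.28), fell by both counts, also adjusted over the list alone (camera adjusted p = 2.98e-06). CXCL5 rose by 1.2 (SE 0.2, adjusted p = 0.000583) and TMEM160 by 2.53 (SE 0.5, adjusted p = 0.00311; 8.47 ± 0.063 against 1.48 ± 0.57 CPM). The noncoding LINC00899 (-0.69) and TOX2 (-0.68) fell, and FAM157C (-0.65) has near copies and is uncertain. Of 27 targets of the oxidative stress factor NRF2 13 rose (14 adjusted over the list alone; 1.07e-07), such as NQO1 (0.52), FTH1 (0.43) and HMOX1 (0.55). Of 24 chemokines 8 rose and 1 fell (10 and 1 adjusted over the list alone; 2.64e-05, adjusted p = 0.0902 with an estimated correlation), such as CXCL3 (0.99). Amino acid response genes fell in 16 of 29 cases and rose in 1 (26 and 2 adjusted over the list alone). Their camera adjusted p was 1.32e-12, and 0.152 with an estimated correlation. The inflammatory calprotectin subunits S100A8 (1.43, 0.0452) and S100A9 (1.22, 0.0464), the receptor CLEC5A (1.0, 0.0133), INHBE (-0.69, 0.0289) and LINC02887 (-0.67, 0.00655) lost their calls without single libraries. Without atractylodes at 500 µg/mL replicate 3 their adjusted p values were 0.277, 0.295, 0.105, 0.212 and 0.073, and without vehicle replicate 3 they were 0.161, 0.17, 0.06, 0.204 and 0.0992. Without vehicle replicate 1 the first 4 were at 0.169, 0.19, 0.0842 and 0.0716, and without atractylodes at 500 µg/mL replicate 1 S100A8 and S100A9 were at 0.0553 and 0.0508. In all 1551 genes passed (797 higher, 754 lower, but 706 higher and 970 lower with GC and length correction). The count was 398 and 593 without vehicle replicates 1 and 3, 283 without atractylodes at 500 µg/mL replicate 3, 481 in a fit of only the compared groups and 1033 with the gradient covariate.

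Atractylodes at 125 µg/mL gave 1692 genes (894 higher, 798 lower). HLA-DRA, which presents antigen on class II molecules, was higher (0.68, adjusted p = 0.00555), but at 0.0569 without atractylodes at 125 µg/mL replicate 1 and 0.132 in a fit of only the compared groups. RIMBP3B (0.61) was at 0.0566, 0.101 and 0.0866 without vehicle replicates 1 and 3 and atractylodes at 125 µg/mL replicate 2. CCDC85B (0.61) was at 0.102 and 0.0737 without vehicle replicate 1 and atractylodes at 125 µg/mL replicate 3. The haem transporter ABCB6 (-0.73) was at 0.0572 and 0.0593 without vehicle replicate 3 and atractylodes at 125 µg/mL replicate 2. FAM157C (-0.75) and the antisense KLC1-AS1 (-0.73) are uncertain because of shared reads. Interferon-induced genes were higher in 13 of 30 cases (20 adjusted over the list alone; camera adjusted p = 1.84e-10, adjusted p = 0.295 with an estimated correlation), such as OAS1 (0.32) and IFIT1 (0.48). Class II genes were higher in 7 of 13 (10 adjusted over the list alone; 1.4e-06, adjusted p = 0.289 with an estimated correlation), such as CD74 (0.29). The total was 824 and 864 without vehicle replicates 1 and 3, 785 and 1026 without atractylodes at 125 µg/mL replicates 1 and 2, and 857 with the gradient covariate. With GC and length correction it was 1043, of which 410 were higher and 633 lower.

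Between the atractylodes concentrations, groups of different label sets, 508 genes differed (221 higher, 287 lower). MT2A was higher at 500 µg/mL (0.96, SE 0.095, adjusted p = 4.89e-08), and 5 of 8 metallothionein and zinc genes rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.2e-07), with MT1X at 1.09. CXCL5 (1.2) was at 0.113 in a fit of only the compared groups, COL12A1 (0.82) at 0.0689 without atractylodes at 125 µg/mL replicate 3, and the immediate-early transcription factor gene EGR3 was at -0.59. PCDHGC4 (-0.75) and the pseudogene IMPDH1P10 (-0.58, uncertain) lost their calls without 4 and 5 of the 6 libraries. The count was 172, 289, 237, 333 and 180 without atractylodes at 500 µg/mL replicates 1 and 2 and at 125 µg/mL replicates 1, 2 and 3, and 855 with the gradient covariate. It was also higher without the low-count filter and with DESeq2, as given below.

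Licorice at 500 µg/mL changed 7145 genes (3648 higher, 3497 lower; 39.4% of those tested, 644 of them at least 2-fold), the highest count of the 11 treatments. With the gradient covariate it was 4936, below BJIKT (6231), ginseng (5676) and the mixture (4982) at 500 µg/mL. HMOX1 (chromosome 22, 35380361 to 35394214) rose by 1.74 (SE 0.08, adjusted p = 7.38e-16; 306 ± 4.9 against 91.6 ± 3.2 CPM), STC1 by 2.08, the small GTPase RRAD by 1.92 and CXCL3 by 1.81. SORL1 (chromosome 11, 121452203 to 121633693) fell by 2.38 (9.19 ± 1.9 against 47.4 ± 1.3 CPM), LONRF2 by 2.15, STC2 by 2.12, the adhesion receptor ADGRD1 by 2.11 and the complement receptor VSIG4 by 1.96 (4.41 ± 0.61 against 17.1 ± 2.7 CPM). TMEM160 rose by 2.20 (adjusted p = 0.00134). The 10 most abundant genes took 11.96% ± 0.276 of the counts against 9.938% ± 0.0372 in vehicle (exact two-sided permutation p = 0.1, the smallest possible).

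Cell cycle genes fell in 34 of 34 cases with licorice at 500 µg/mL, also adjusted over the list alone (camera adjusted p = 3.29e-27), such as CCNB2 (-1.13), E2F1 (-1.14) and KIF11 (-1.25). Unfolded protein response genes rose in 18 of 20 cases (19 adjusted over the list alone; 6.65e-17), such as HSPA5 (0.92), MANF (0.89) and HYOU1 (0.50). Cholesterol synthesis genes rose in 22 of 24 cases by both counts (3.13e-13), such as SQLE (0.56), MSMO1 (0.58) and INSIG1 (0.64). Fatty acid synthesis genes rose in 12 of 14 (13 adjusted over the list alone; 1.38e-08), such as SCD (0.65) and FASN (0.53). Of 27 NRF2 targets 20 rose and 2 fell (21 and 2 adjusted over the list alone; 1.38e-11), such as TXNRD1 (0.78) and SRXN1 (0.69). Lysosome and autophagy genes rose in 23 of 30 cases and fell in 2 (24 and 2 adjusted over the list alone; 2.72e-07), such as NEU1 (0.79) and the protease CTSL (0.82). Metallothionein and zinc genes fell in 6 of 8 cases and rose in 1 by both counts (0.000539), with MT2A at -1.78, MT1F at -1.99 and SLC30A1 at -0.87. M2 markers fell in 8 of 19 cases and rose in 3 (9 and 3 adjusted over the list alone; 0.0101), such as FN1 (-1.49) and the lectin CLEC7A (-1.94). Interferon-induced genes fell in 22 of 30 cases and rose in 2 by both counts (2.87e-07, adjusted p = 0.236 with an estimated correlation), such as IFIT1 (-1.11).

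**Figure D2:**
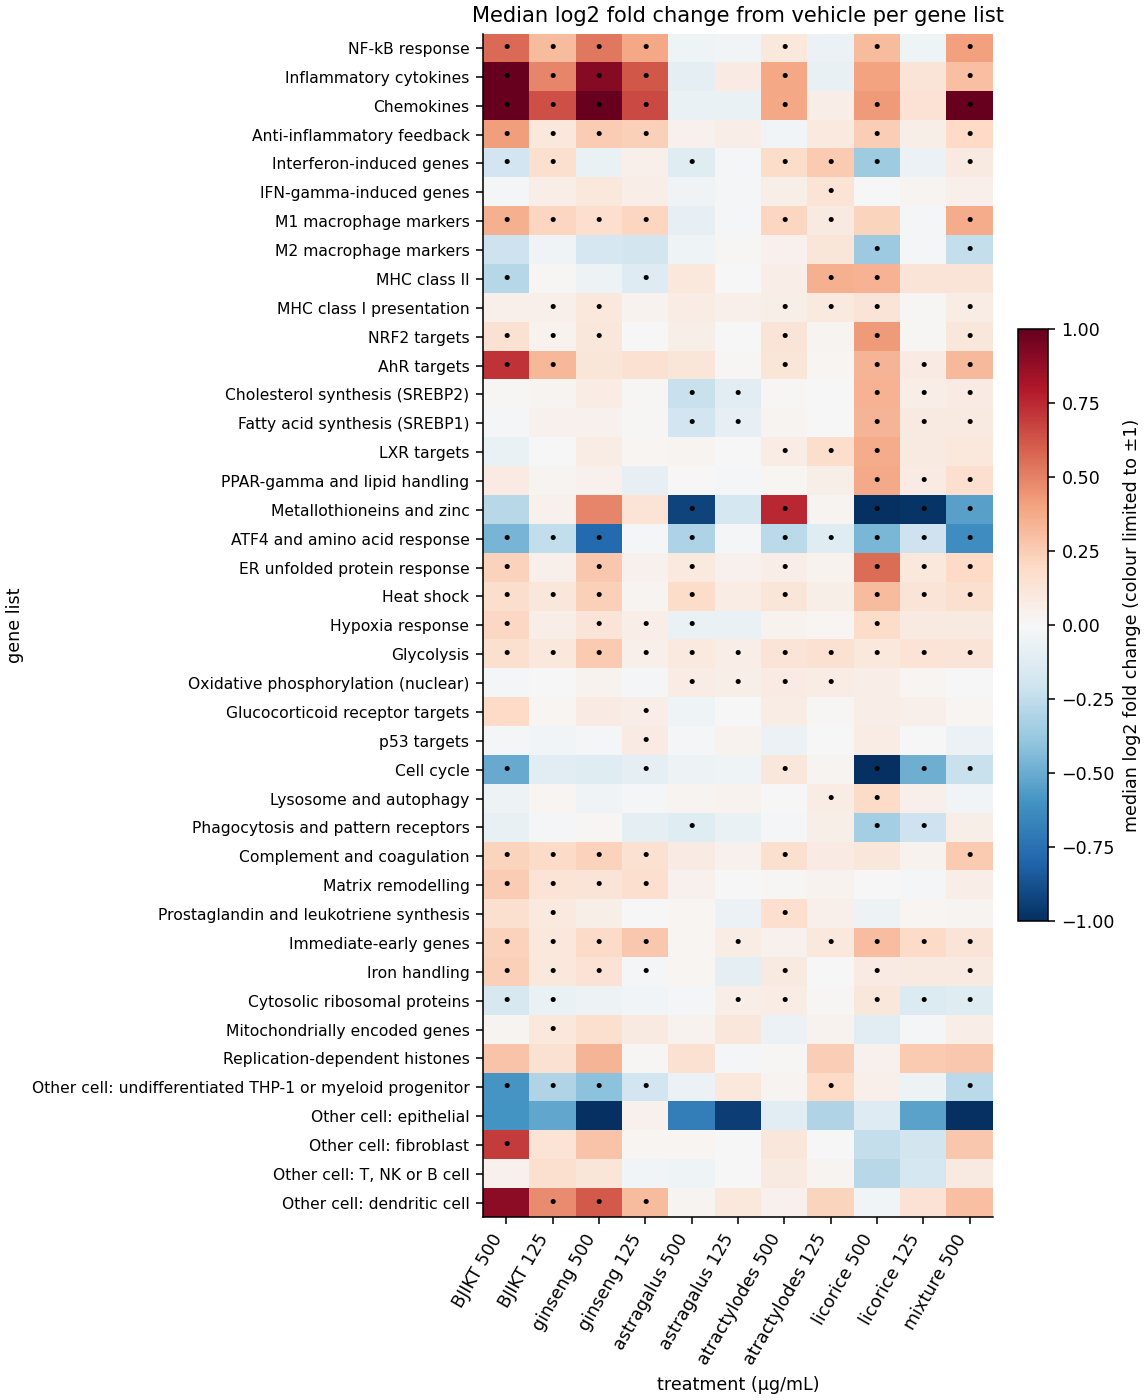
Median log2 fold change from vehicle of the tested members of 41 gene lists (lines) in 11 treatments (columns), with colours limited to -1 and 1 and a dot where camera with the preset correlation of 0.01 gave an adjusted p under 0.05. Chemokines rise with BJIKT, ginseng and the mixture (median 1.08), and also with atractylodes at 500 µg/mL (0.383). Metallothioneins fall with licorice at both concentrations, astragalus at 500 µg/mL and the mixture, and rise with atractylodes at 500 µg/mL. Cell cycle genes fall with licorice at 500 µg/mL (median -1.1), among others.

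Licorice at 125 µg/mL gave 3171 genes (1569 higher, 1602 lower). MT2A fell by 1.47 (SE 0.12, adjusted p = 4.19e-11; 2.28 ± 0.13 against 6.34 ± 0.65 CPM) and the signalling inhibitor SPRY1 by 1.3, while the stromelysin MMP3 rose by 1.2 and TMEM160 by 2.29. C4orf48 (1.74) was at 0.0518 without licorice at 125 µg/mL replicate 1, 0.168 in a fit of only the compared groups and 0.231 with the gradient covariate. PTGES (-1.34) was at 0.0885 without vehicle replicate 2, 0.065 and 0.0891 without licorice at 125 µg/mL replicates 1 and 2 and 0.157 with the covariate. Metallothionein and zinc genes fell in 6 of 8 cases and rose in 1 by both counts, also adjusted over the list alone (camera adjusted p = 1.13e-05). Cell cycle genes fell in 21 of 34 (22 adjusted over the list alone; 6.76e-14, adjusted p = 0.12 with an estimated correlation), such as PLK1 (-0.87). The count of 3171 was 1894 without licorice at 125 µg/mL replicate 2 and 1592 with the gradient covariate.

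The pair of licorice concentrations, within 1 label set, differed in 5440 genes (2835 higher, 2605 lower). HMOX1 was higher at 500 µg/mL (1.22, adjusted p = 1.95e-12), LONRF2 (-2.14), SORL1 (-1.70) and ADGRD1 (-1.62) were lower. FAM156B (1.34, uncertain because of a near copy) was at 0.0675 and 0.0527 without replicate 3 of licorice at 500 and at 125 µg/mL, and PTGES (1.28) between 0.0538 and 0.0741 without 4 single libraries. Unfolded protein response genes were higher in 19 of 20 cases by both counts, also adjusted over the list alone (camera adjusted p = 2.41e-18). NRF2 targets were higher in 22 of 27 (2.47e-17) and cholesterol synthesis genes in 22 of 24 with 1 lower (2.41e-14), all with the same counts adjusted over the list alone. Cell cycle genes were lower in 33 of 34 by both counts (2.26e-22). Ribosomal protein genes were higher in 32 of 36 cases (33 adjusted over the list alone; 4.91e-13, adjusted p = 0.111 with an estimated correlation).

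The 4 ingredients were compared with each other at 500 µg/mL in a joint test, in which 9661 genes differed, 1144 of them by at least 1 on the log2 scale between the highest and lowest ingredient. The homing receptor CCR7 had the smallest p (adjusted p = 1.52e-25), with 40.2 ± 2.1 CPM in ginseng, 8.97 ± 0.42 in astragalus, 12 ± 0.89 in atractylodes and 21.1 ± 0.47 in licorice (n = 3 each). MT2A (range 2.75, adjusted p = 3.1e-23) had 11.9 ± 0.63, 2.42 ± 0.33, 12.4 ± 1.4 and 1.84 ± 0.11 CPM in the same order, and CCL1 (range 4.84) 48.5, 4.78, 5.42 and 1.68 CPM. The nuclear cofactor ANKRD1 (range 1.47), TRAF1 (1.07) and the membrane protein PERP (1.05) were highest in ginseng, the receptor PDGFRA (1.74) was highest in ginseng and lowest in licorice, and SLC30A1 (1.09) was highest in atractylodes at 154 CPM and lowest in licorice at 72.3 CPM. Ginseng at 500 µg/mL lies in set 1, astragalus and atractylodes in set 2 and licorice in set 3, so only astragalus and atractylodes were compared within a set.

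**Figure D3:**
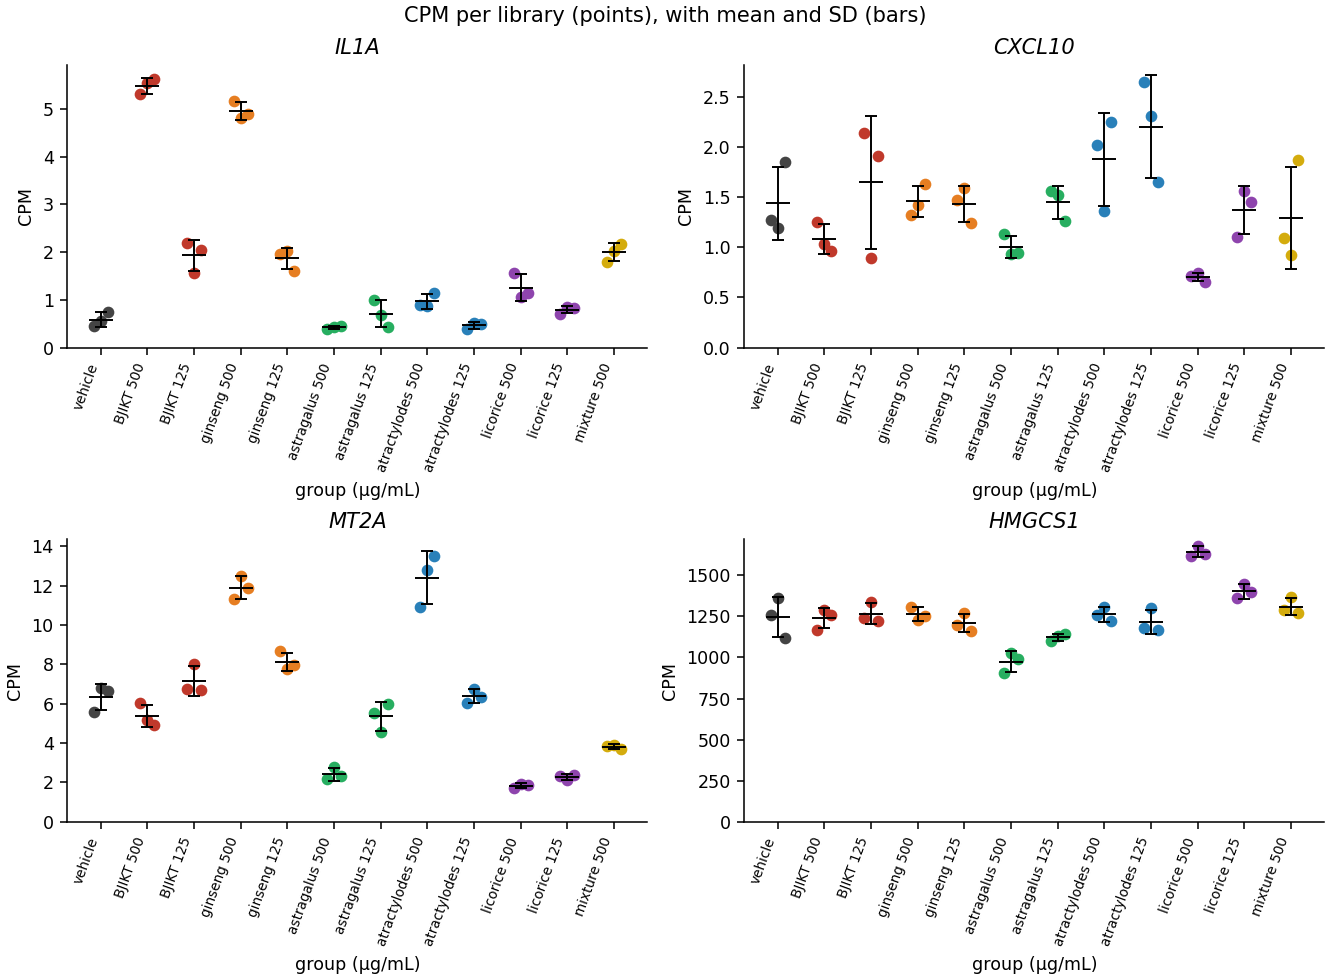
CPM of IL1A, CXCL10, MT2A and HMGCS1 in each of the 36 libraries, 1 point per library, with the mean and SD of each group of 3. MT2A is lowest in licorice at 500 and 125 µg/mL and astragalus at 500 µg/mL (means 1.84, 2.28 and 2.42 CPM) and highest in atractylodes and ginseng at 500 µg/mL (12.4 and 11.9 CPM), against 6.34 CPM in vehicle.

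The mixture of the 4 ingredients was compared with vehicle to set the main ingredients beside the whole decoction. STC1 (log2FC 2.30), CXCL5 (2.15), TMEM160 (2.08), PTGS2 (1.94), S100A8 (1.91, SE 0.43, adjusted p = 0.00158), the uncertain paralog CCL4L2 (1.86) and CCL1 (1.84) rose. RN7SL2 (1.80), a signal recognition particle RNA with near copies, is uncertain. It was at an adjusted p of 0.0825 without mixture replicate 3 and 0.086 in a fit of only the compared groups. NUPR1 (-1.64), STC2 (-1.61), PHGDH (-1.59), PSAT1 (-1.57), ASNS (-1.53), the natural killer ligand ULBP1 (-1.48), KCTD15 (-1.44) and the arginine synthesis enzyme ASS1 (-1.36) fell. TNF rose by 1.59, IL1B by 1.41 (1740 CPM against 653), CXCL8 by 1.5, CD80 by 1.43, HMOX1 by 0.91 and CYP1B1 by 0.86, and MT2A fell by 0.73. IL6 rose by 2.90 at a very low level (0.328 to 0.511 CPM against 0.0239 to 0.108 in vehicle). CXCL10 (-0.15, adjusted p = 0.713), CD163 (-0.17, 0.402) and HMGCS1 (0.07, 0.37) did not pass. CCL2 (0.87, 0.0356) was at 0.187, 0.0814, 0.0882 and 0.115 without vehicle replicates 2 and 3 and mixture replicates 2 and 3. CD86 (0.46, 0.0369) was at 0.115, 0.117, 0.0931 and 0.116 without vehicle replicates 1 and 3 and mixture replicates 2 and 3. For CCL2 and CD86 DESeq2 gave 0.0659 and 0.0575.

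Amino acid response genes fell in 25 of 29 cases with the mixture and rose in 2 (26 and 3 adjusted over the list alone; camera adjusted p = 8.04e-21). NF-κB genes rose in 18 of 22 cases by both counts (1.41e-14). Chemokines rose in 13 of 24 with 1 lower (14 and 1 adjusted over the list alone; 5.3e-10), such as CCL3 (1.39) and CXCL2 (1.47). M1 markers rose in 16 of 23 with 1 lower by both counts (2.17e-07) and AhR targets in 6 of 7 with 1 lower by both counts (0.000213). In all 5048 genes passed, 2490 higher and 2558 lower.

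Response profiles were compared with that of BJIKT at 500 µg/mL across 18154 genes, which are not independent replicates. The correlation of log2FC was 0.778 for ginseng at 500 µg/mL and 0.713 for the mixture, against 0.493 and 0.496 simulated for unchanged groups that share the vehicle libraries, 0.573 for licorice (0.489), 0.407 for atractylodes (0.501) and 0.349 for astragalus (0.502). Covariances were 0.127, 0.105, 0.101, 0.0458 and 0.0394 in the same order against about 0.0246 to 0.0249 simulated, so that the differences were 0.103, 0.0799, 0.0763, 0.0212 and 0.0147. Ginseng shared 2076 higher and 1988 lower genes with BJIKT (498 and 491 for independent lists) with 31 in opposite directions, the mixture 1787 and 1785 (411 and 431) with 19 opposite, and licorice 1799 and 1826 (603 and 590) with 273 opposite. Atractylodes shared 427 and 398 (132 and 127) with 85 opposite, and astragalus 557 and 502 (184 and 173) with 168 opposite. The 3 vehicle libraries cannot be split into parts of at least 2, so part of each excess may come from the shared controls. BJIKT and ginseng at 500 µg/mL lie in set 1 with vehicle, and the mixture, licorice, atractylodes and astragalus in sets 2 and 3. A difference between sets can enter the profiles of the latter but not that of ginseng, and the simulations held none. Likeness to BJIKT and label set therefore cannot be told apart in the order of these values.

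Set directly against BJIKT at the same total of 500 µg/mL, the mixture had lower inflammatory and higher interferon-induced transcripts. INHBA, an activin subunit, was lower (-1.14; 203 against 448 CPM, adjusted p = 3.79e-09), as were CCL1 (-1.25), STC1 (-1.25), the chemokine CCL22 (-1.19), the noncoding MIR124-1HG (-1.15) and the integrin ITGA1 (-1.15), while CPVL (0.91), FABP4 (0.89) and HLA-DRA (0.84) were higher. BLOC1S5-TXNDC5 (4.17), RN7SL2 (1.6) and RN7SL1 (1.36), all uncertain because of shared reads, each lost their calls without 5 of the 6 libraries (adjusted p 0.0504 to 0.18, 0.062 to 0.236 and 0.0618 to 0.19) and in a fit of only the compared groups (0.118, 0.148 and 0.108). Of 24 chemokines 13 were lower (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 4.6e-09), such as CXCL8 (-0.85). Of 17 cytokines 9 were lower (10 lower and 1 higher adjusted over the list alone; 2.63e-06), such as IL1A (-1.45), and of 7 AhR targets 5 were (6 adjusted over the list alone; 5.19e-07). Interferon-induced genes were higher in 24 of 30 cases (27 adjusted over the list alone; 4.88e-19), such as IFIT2 (0.72). Cell cycle genes were higher in 18 of 34 (25 adjusted over the list alone; 7.4e-16) and class II genes in 8 of 13 (10 adjusted over the list alone; 1.52e-06, adjusted p = 0.0979 with an estimated correlation). There were 2008 genes (900 higher, 1108 lower), 1223 without BJIKT at 500 µg/mL replicate 2 and 1292 without mixture replicate 3. The groups lie in different label sets.

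Whether the mixture's change equals the sum of the changes of its components at 125 µg/mL was tested on the log2 scale. In 1088 genes it did not, 464 with a higher and 624 with a lower value than the sum. SPRY1 (2.08, SE 0.47, adjusted p = 0.00718), the receptor-like TMEM119 (2.06, 0.0388), ZNG1F (1.94, 0.026, uncertain because of near copies) and the phosphodiesterase PDE4B (1.77, 0.0311) lay above the sum, and TMEM160 (-5.97, SE 1.4, 0.0162), ZFPM1 (-2.57, 0.00889), the transcription factor TBX21 (-2.30, 0.000605) and TPGS1 (-2.27, 0.00286) below it. With the library gradient as covariate, which is built on TMEM160 and is no test of it, the other 7 lost their calls (0.157 to 0.778) and 8 genes in all passed. The score was lower in vehicle (-0.317 to -0.09) than in most libraries of the mixture and its components. Fewer calls with the covariate may therefore also come from lost precision. Vehicle lies in set 1 and the mixture and its components in sets 2 and 3, so a difference between sets enters the sum 4 times and the mixture once. Set and departure from the sum cannot be told apart here. Without vehicle replicates 1, 2 and 3 the counts were 325, 545 and 597, a fit of only the compared groups gave 1648, and GC and length correction changed the split to 395 higher and 351 lower. TMEM160 was at 0.0969 and 0.0608 without vehicle replicates 1 and 2, ZFPM1 at 0.0753 without vehicle replicate 1, and ZNG1F at 0.0509, 0.121 and 0.067 without vehicle replicates 1, 2 and 3. PDE4B was at 0.211, 0.0535 and 0.0521 without vehicle replicates 2 and 3 and ginseng at 125 µg/mL replicate 3, and TMEM119 between 0.0519 and 0.213 without 10 single libraries.

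**Figure D4:**
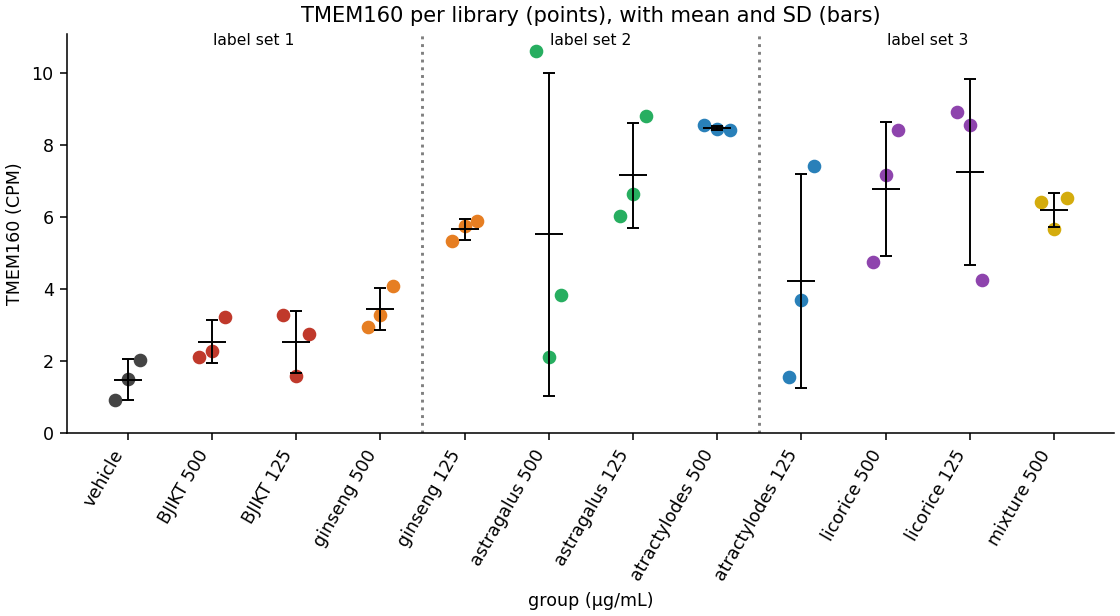
CPM of TMEM160 in each of the 36 libraries, 1 point per library, grouped by treatment and marked by label set. The libraries of set 1, vehicle among them, lie between 0.908 and 4.09 CPM, those of set 2 between 2.11 and 10.6 CPM and those of set 3 between 1.55 and 8.91 CPM.

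Markers of other cells were tested in every comparison. Markers of undifferentiated THP-1 cells or myeloid progenitors fell in 7 of 11 cases with BJIKT at 500 µg/mL by both counts (camera adjusted p = 3.54e-05), such as the granule protein AZU1 (-0.63) and the factor MYB (-1.14). They also fell with ginseng at 500 µg/mL (7 of 11, 0.00389, adjusted p = 0.0573 with an estimated correlation), beside the lower cell cycle genes of BJIKT. They fell with BJIKT at 125 µg/mL (5 of 11; 0.00577, adjusted p = 0.071 with an estimated correlation, and 0.0574 without BJIKT at 125 µg/mL replicate 1) and ginseng at 125 µg/mL (2 of 11, 7 adjusted over the list alone; 0.017, adjusted p = 0.0951 with an estimated correlation). With the mixture 6 fell and 1 rose (7 and 1 adjusted over the list alone; 0.0311, adjusted p = 0.127 with an estimated correlation, and 0.0657 and 0.067 without vehicle replicate 2 and mixture replicate 2). With atractylodes at 125 µg/mL 4 rose (5 adjusted over the list alone; 0.0228, adjusted p = 0.289 with an estimated correlation, and 0.057 without vehicle replicate 1). Against BJIKT the mixture had 5 of the 11 higher (6 adjusted over the list alone; 5.01e-05). Dendritic cell markers rose in 4 of 9 cases and fell in 1 with ginseng at 500 µg/mL (0.0289, adjusted p = 0.0573 with an estimated correlation), among them CCR7 (1.68) and the chemokine CCL22 (1.53), which also stand in the chemokine or M1 lists. They were also called with ginseng at 125 µg/mL, where 2 rose and 1 fell by both counts (0.0155), and with BJIKT at 125 µg/mL, where 2 rose (4 adjusted over the list alone; 0.049, adjusted p = 0.0979 with an estimated correlation). The last was at 0.0681, 0.0524 and 0.162 without vehicle replicates 2 and 3 and BJIKT at 125 µg/mL replicate 1. Between the astragalus concentrations the dendritic cell list was lower at 500 µg/mL, with 1 of 9 members down (2 adjusted over the list alone). Its camera adjusted p was 0.00985, and 0.0351 with an estimated correlation. Fibroblast markers rose in 3 of 6 cases with BJIKT at 500 µg/mL by both counts (0.0195), namely PDGFRA (0.92), FAP (0.78) and PDGFRB (0.61). Between the atractylodes concentrations the fibroblast list was higher at 500 µg/mL, with 1 of 6 members up (2 adjusted over the list alone). Its camera adjusted p was 0.0154, and 0.0742 with an estimated correlation. Epithelial markers (5 measured; adjusted p 0.214 to 0.84 over the 11 comparisons with vehicle) and T, NK or B cell markers (8 measured; 0.1 to 0.955) were not called in any of them, and with licorice at 500 µg/mL none of the 5 lists was (0.1 to 0.98).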

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

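The tests of the zinc relation, of less sterol and of a difference between the label sets, and the alternatives with GC and length correction and with the library gradient as covariate, were chosen after the results were seen, while the comparison of dose effects between extracts was set before the data were examined.

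The change of a gene list from 125 to 500 µg/mL was compared between extracts (410 tests, adjusted p with an estimated correlation), and 9 cases are given because a list was called in opposite directions in a pair of extracts and the difference itself passed. In several of them few members passed on 1 side, or the call of 1 extract was lost with an estimated correlation. Of 8 metallothionein and zinc genes 3 fell and 1 rose with astragalus (6 and 1 adjusted over the list alone; median -0.733), and 5 rose with atractylodes (7 rose and 1 fell adjusted over the list alone; median 0.585; adjusted p of the difference 0.000167). With ginseng 3 rose and 1 fell by both counts (median 0.273; difference from astragalus 0.00214), a call with adjusted p = 0.111 with an estimated correlation. Of 24 cholesterol synthesis genes 7 fell with astragalus (16 adjusted over the list alone; median -0.154), while 22 rose and 1 fell with licorice by both counts (0.285; difference 0.00826). Of 14 fatty acid synthesis genes 3 fell with astragalus (6 adjusted over the list alone; -0.0868) and 12 rose with licorice by both counts (0.262; difference 0.00422).

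Of 30 lysosome and autophagy genes 2 fell with atractylodes (4 adjusted over the list alone; median -0.0724, adjusted p = 0.0742 with an estimated correlation), while 19 rose and 1 fell with licorice (23 and 1 adjusted over the list alone; 0.154; difference 0.00299). Of 29 immediate-early genes 14 rose and 1 fell with BJIKT (16 and 2 adjusted over the list alone; 0.169) and 2 fell with astragalus by both counts (-0.0621, adjusted p = 0.372 with an estimated correlation; difference 0.00851). Of 34 cell cycle genes 1 rose with atractylodes (2 adjusted over the list alone; 0.115, adjusted p = 0.479 with an estimated correlation). Against this, 31 fell with BJIKT (32 adjusted over the list alone; -0.414; difference 0.0175) and 33 with licorice by both counts (-0.558; difference 0.0175). Of 36 ribosomal protein genes 6 fell with BJIKT (7 adjusted over the list alone; -0.086, adjusted p = 0.38 with an estimated correlation) and 32 rose with licorice (33 adjusted over the list alone; 0.247, adjusted p = 0.111 with an estimated correlation; difference 0.0372). The ginseng and atractylodes concentrations lie in different label sets, so that in the cases with either of them set and concentration cannot be told apart.

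The metallothionein genes lay 2.7 (log2, median of 5; 1.75 to 2.75) higher in atractylodes than in licorice at 500 µg/mL. The difference was 2.75 (1.79 to 2.79) after GC and length correction and 2.64 (1.76 to 2.75) with the gradient as covariate, which argues against either as the whole source. A candidate explanation is a change in the zinc available to the cells: over the 12 group means the importer SLC39A10 went against the metallothioneins (r = -0.77, permutation p = 0.0034) and the exporter SLC30A1 with them (r = 0.776, p = 0.0023), and -0.686 and 0.703 without both licorice groups. Within set 3 atractylodes at 125 µg/mL lay 1.79 (0.66 to 2.16) above licorice at 500 µg/mL, and within set 2 atractylodes lay 1.95 (1.91 to 3.76) above astragalus at 500 µg/mL, with all 3 libraries above all 3 in 5 of 5 members each, which argues against a difference between the label sets as the whole source, though a part stays open. The 12 groups hold the same extracts at both concentrations and a mixture of 4 of them. They are therefore not independent, and the permutation p of the zinc relation may be too small. The zinc explanation is a hypothesis tested on the data that raised it, and zinc was not measured.

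The cholesterol synthesis genes lay 0.63 (log2, median of 24; -0.27 to 0.94) higher in licorice than in astragalus at 500 µg/mL. The difference was 0.61 (-0.35 to 0.9) after GC and length correction and 0.66 (-0.24 to 0.95) with the gradient as covariate, which argues against either as the whole source. Less sterol in the licorice cells would lower the sterol-induced LXR targets, but 3 of 3 rose (ABCA1 0.47, ABCG1 1.14, MYLIP 0.42), which argues against it. This prediction was written after the results were seen and sterol was not measured, so less sterol is not excluded. Within single sets the genes rose with the licorice concentration and fell with that of astragalus, both called with an estimated correlation (0.0189 and 0.0351), and these changes differed by 0.47 (-0.06 to 0.85; above 0 in 23 of 24), which argues against a difference between the label sets as the whole source, though a part stays open.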

How the results depend on the processing

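GC and length correction and the library gradient covariate were chosen after the results were seen, and the other alternatives before the data were examined; the cause of a change was not tested unless stated.

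With DESeq2's size factors in edgeR (RLE) and with replicate number as a block, 19 of 19 gene counts stayed within 1.5 times. Replicate numbers did not pair the samples (mean r 0.051 for the same number, -0.025 for others; 1 of 17 comparisons, astragalus at 500 µg/mL, had every pair above 0.1, with 2359 genes in the block fit against 2138). Without the low-count filter there were 801 genes for astragalus at 125 µg/mL, 652 and 1114 between the astragalus and the atractylodes concentrations and 1723 for the mixture against the sum. DESeq2 gave 622, 446 and 811 for the first 3. Fits of only the compared groups, which have fewer samples, gave 864 for BJIKT at 125 µg/mL, 1359 and 126 for astragalus at 500 and 125 µg/mL, 481 for atractylodes at 500 µg/mL and 1648 for the mixture against the sum. GC and length correction gave 122 for astragalus and 1043 for atractylodes at 125 µg/mL. With it the more frequent direction turned from higher to lower for BJIKT at 125 µg/mL (941 higher, 1070 lower), ginseng at 500 (2925, 3283), atractylodes at 500 (706, 970) and 125 (410, 633), licorice at 500 (3457, 3916) and between the BJIKT (1511, 1597) and licorice concentrations (2641, 2872). It turned from lower to higher between the ginseng (1815, 1740) and astragalus concentrations (189, 187) and for the mixture against the sum (395, 351). RLE and DESeq2 turned it from lower to higher for BJIKT at 500 µg/mL (3113, 2967 and 2994, 2730), licorice at 125 (1687, 1501 and 1786, 1431), the mixture (2617, 2449 and 2567, 2281) and between the ginseng concentrations (1584, 1568 and 1643, 1599). It also turned in 7 comparisons without the filter, 3 in fits of only the compared groups, 2 with the gradient covariate and 1 with the block, so which direction is more frequent depends on the scaling and other settings in these comparisons. Over the genes with a mean log2 CPM of at least 3 the correlation of the mixture with BJIKT moved from 0.713 to 0.844, and the other 4 by less than 0.1. The gradient covariate gave 982 for ginseng, 4 for astragalus, 857 for atractylodes and 1592 for licorice at 125 µg/mL, 1033 for atractylodes at 500 µg/mL, 855 between the atractylodes concentrations and 8 for the mixture against the sum. The median score was -0.0893 in set 1, 0.0561 in set 2 and 0.0551 in set 3. The score thus partly follows label set and treatment, and lower counts with it may also reflect lost precision. With it the oxidative phosphorylation list was called as lower in ginseng at 125 µg/mL (camera adjusted p = 0.0327, written with the sign of its direction as -0.0327). Without the covariate camera pointed up (mean log2FC 0.0176, median -0.0122), but the list was not called (camera adjusted p = 0.699). The direction of this list thus turned, but no result called without the covariate did. The score contains the list members COX5A and CYC1, for which the covariate is no test. With an estimated correlation 182 of 697 list results were weaker and 515 the same.

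Leaving out 1 library, where a lone pair is assumed to vary like the other groups, gave 4938 to 5389 genes for BJIKT at 500 µg/mL and 1045 to 1866 at 125, 5048 to 5554 and 1127 to 1433 for ginseng, 1289 to 1874 and 23 to 222 for astragalus, 283 to 2222 and 785 to 1695 for atractylodes, 6310 to 6735 and 1894 to 2651 for licorice. It gave 3837 to 4390 for the mixture. Between concentrations it gave 1812 to 2864 for BJIKT, 2293 to 2700 for ginseng, 89 to 223 for astragalus, 172 to 353 for atractylodes and 4469 to 4684 for licorice. It gave 1223 to 1595 for the mixture against BJIKT, 325 to 1260 against the sum and 9027 to 9531 for the 4 ingredients.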

Other observations

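The tests of the treatments and of a difference between the label sets, and of other splits for BJIKT at 500 µg/mL, were chosen after the result was seen.

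Licorice at 500 µg/mL also moved lipid handling and uptake genes. Of 18 PPARγ and lipid handling genes 12 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 1.89e-06). Of 16 targets of the sterol receptor LXR 9 rose and 3 fell by both counts (0.002), such as the lipid droplet protein PLIN2 (0.89) and NR1H3 (1.05). Phagocytosis genes fell in 17 of 29 cases and rose in 4 by both counts (0.00233, adjusted p = 0.186 with an estimated correlation and 0.0741 with the gradient covariate), with the scavenger receptor MARCO at -3.03 and the Fc receptor FCGR1A at -1.10.

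BJIKT at 500 µg/mL raised immediate-early genes in 19 of 29 cases and lowered 3 (20 and 3 adjusted over the list alone; camera adjusted p = 8.62e-08), such as FOSB (1.73) and DUSP4 (0.83). It raised complement and coagulation genes in 13 of 28 with 7 lower (13 and 9 adjusted over the list alone; 0.000678), such as the anticoagulant receptor THBD (1.91) and THBS1 (2.14). NRF2 targets rose in 14 of 27 cases and fell in 3 (15 and 3 adjusted over the list alone; 9.35e-06, adjusted p = 0.0538 with an estimated correlation), such as NQO1 (0.80).

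TMEM160, UQCRFS1P1 and UQCRFS1 were higher than in vehicle in the 8 groups of label sets 2 and 3 (24 values; median log2FC 2.14, 0.12 to 5.53; 17 passed). After GC and length correction the median was 2.01 (0.12 to 5.46, 17 passed), which argues against that trend as the whole source. UQCRFS1P1 is a pseudogene that shares reads with UQCRFS1. It was near the floor in vehicle (0.0239 to 0.0538 CPM), so its log2FC are uncertain. In set 1 it was above vehicle in every treated library (0.13 to 0.767 CPM). TMEM160 was above vehicle (0.908 to 2.04 CPM) in ginseng (2.94 to 4.09) and BJIKT at 500 µg/mL (2.12 to 3.22). TMEM160 in BJIKT at 125 µg/mL (1.59 to 3.27) and UQCRFS1 in BJIKT overlapped vehicle. UQCRFS1 in ginseng at 500 µg/mL (74 to 74.5 CPM) lay narrowly above vehicle (64.8 to 73.1 CPM). For UQCRFS1P1 and TMEM160, and by a narrow margin for UQCRFS1, the rise is thus not confined to sets 2 and 3. The 8 treatments held 34.6% of the variance of TMEM160 among the 24 libraries (random assignments 30.5%, permutation p = 0.33), which decides nothing. The 4 group means of TMEM160 in set 1 differed from the other 8 by -1.32 log2 (exact permutation p = 0.00202, the smallest that 495 assignments can give). The gene was picked for this pattern, so the p is no independent support. In sets 2 and 3, 4 libraries lay at or below the highest of set 1. Treatments and label sets cannot be told apart here, since each treatment lies in 1 set.

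Other splits of the same libraries were counted in edgeR fits of only the compared groups. For 2 designs with 40 splits only the real split (1 of 40, a share under 0.05) gave as many genes. For the 4 ingredients at 500 µg/mL it gave 8627 (highest other 1264). For the mixture against the sum it gave 1648 by edgeR (highest other 0), and no other tool was run on the splits. At an unadjusted p under 0.05 it gave 4051 genes there, against at most 2121 in other splits. The other splits put libraries of different treatments into 1 group, which widens the spread within groups. For the mixture they therefore ask whether the groups differ at all, and cannot decide whether the changes add up. These splits cannot separate label set from treatment, and the count for the mixture against the sum, 1088 in the fit of all libraries, was 8 with the gradient covariate and 325, 545 and 597 without vehicle replicates 1, 2 and 3. For the other 17 the 10 splits are too few for a share under 0.05. Real counts against vehicle were 5818 and 864 for BJIKT at 500 and 125 µg/mL, 4758 and 1467 for ginseng, 1359 and 126 for astragalus, 481 and 1144 for atractylodes, 6717 and 2729 for licorice and 4856 for the mixture. They were 2205, 2531, 190, 468 and 5549 between the concentrations of BJIKT, ginseng, astragalus, atractylodes and licorice and 2876 for the mixture against BJIKT, with at most 3 genes in any other split.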
